A study of Mus musculus with 11 samples.

How the data were processed

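Total RNA from whole kidney and lung tissue of adult BALB/c mice, all labelled female, was measured on 11 Illumina bead arrays. The groups were healthy kidney (n = 3), fibrotic kidney after unilateral ureter obstruction (n = 2), healthy lung (n = 3) and fibrotic lung after intratracheal bleomycin (n = 3). Each array of a group came from a separate mouse, per the design text in the labels, so the spread within a group includes the spread between mice. The titles and the design text give the healthy kidneys and healthy lungs as organs of the same 3 mice, whereas the description fields number the mice separately for each array; the titles were followed.

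RNA was extracted with Trizol, checked on a Bioanalyzer and turned into biotin-labelled cRNA with the Ambion MessageAmp kit, per the labels' protocols. GenomeStudio 5.0 was used, per the submitters' processing notes. The deposited table gives a raw bead intensity and a detection p-value for each of 45281 probes on each array. The authors' detection p-value compares a probe with the array's negative controls, which were not used here as separate values. The authors also deposited processed intensities for the same arrays. On every array these were a straight line of the raw intensity to within rounding, so they are linear, background-subtracted, scaled by 1 factor per array and not centred on genes, and no scale or direction stayed unknown. Their medians were 28.4, 28.8 and 23.4 in the healthy kidneys, 16.8 and 16.2 in the fibrotic kidneys, 10.9, 10.9 and 10.6 in the healthy lungs, and 18.6, 24.7 and 16.4 in the fibrotic lungs. Slide and scan date are not given in the sources used here, so neither was tested as a batch.

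Of the probes, 34885 carried 1 gene symbol in the platform annotation, 18 carried several and 10378 carried none. No gene was named from the last 2 kinds. A reference gene was found for 34807 probes, and 0 symbols changed. Annotated symbols are those of the array's design, and probes of near-identical genes can take up each other's transcripts.

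From the raw intensities, the background was corrected and the arrays were quantile normalised with neqc in limma 3.58.1 under R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16. Levels are on the log2 scale that results. Probes with a detection p-value under 0.05 on at least 2 arrays were kept, 24396 in all, and each gene was represented by its probe with the highest mean over the 11 arrays, which left 12865 genes. A linear model with 1 coefficient per group was fitted over the 11 arrays with lmFit and eBayes (7 residual degrees of freedom, 3.22 prior degrees of freedom). The contrasts were fibrotic against healthy kidney, fibrotic against healthy lung, the kidney change minus the lung change, and healthy kidney against healthy lung. Adjusted p-values are limma's, with the Benjamini-Hochberg method within a contrast, and 0.05 was the threshold. A group mean is given with its SD and a log2 change with the SE of the fit. The small number of arrays limits the precision, and the obstructed kidneys, at 2, most of all.

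Where a gene was not above background on any array of the dimmer group, only a bound can be given. It is written as "at least N-fold": the brighter group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal, as log2 means.

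The 41 gene lists held matrix and fibroblast genes, immune and stromal cell markers, injury genes, parenchymal cell markers of both organs, markers of other tissues that a dissected sample can hold, and metabolic and stress genes. They named 1140 genes, of which 1027 were on the array. Lists were tested with camera in limma at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. A further 5 lists were written after the data were seen and are named as such. Within each contrast their p-values were adjusted over these 5 alone, apart from the 41.

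Before the data were examined, the groups, contrasts, lists, alternative settings and the rule for naming genes were fixed. The rule took, among genes past the threshold whose arrays did not overlap between the groups compared, the 8 largest rises and 8 largest falls of each fibrosis contrast, the 5 and 5 largest of the other contrasts (for the organ difference without the condition on overlap), the 8 largest shared changes per direction by the smaller of the changes, the 3 members with the smallest p of each list described, and a few fibrosis, tubule and lung markers whatever their values. Genes known only by a clone or a predicted-gene name were passed over. Thus a gene named for the size of its fibrosis change moved the same way on every array of its group.

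Alternatives were no background correction, scaling to a common median, the authors' processed intensities (floor of 16, log2), an offset of 50, no filter and a stricter filter (detection p-value under 0.01 on at least 3 arrays), all probes, a mean-variance trend, array weights, a 2-fold threshold, only the arrays compared, the mouse as a block, and leaving out each array in turn. Healthy organs of a mouse were paired by the titles. Deviations from the group means correlated across genes at r = -0.0699, 0.0140 and -0.113 between organs of the same mouse, and the correlation estimated for arrays of 1 mouse was -0.0254.

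The steps were tested on simulated arrays with 200 of the 12865 genes changed. Of genes changed 2-fold, 39% were recovered in the kidney contrast, 46% in the lung contrast, 11% in the organ difference and 63% in the healthy organ contrast; of genes changed 4-fold, 87%, 90%, 67% and 88%. False calls made up 3.82%, 5.56%, 3.70% and 6.79% of the calls, in the same order. The simulated genes varied independently, without array or processing effects, and far fewer were changed than were called in the real data. These rates therefore need not hold for the real data. For 5177 genes with several probes, different probes were called in opposite directions for 208 genes in kidney, 240 in lung, 328 in the organ difference and 317 between the healthy organs.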

Results

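Gene expression was compared between healthy and fibrotic organs in mouse, with kidneys scarred by obstruction of the ureter and lungs scarred by bleomycin, a drug that injures the lung epithelium. Raw median intensity per array lay between 95.2 and 125.1, and 17036 to 21504 probes per array, or 9591 to 11462 of the genes tested, were above background. Over the 12865 genes, arrays of a group correlated at r = 0.935 to 0.988, healthy and fibrotic kidneys at 0.874 to 0.925, healthy and fibrotic lungs at 0.887 to 0.929, and kidneys with lungs at 0.710 to 0.866. The first principal component held 66.8% of the variance and parted the organs. The second held 13.7%.

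The first comparison asked what changed in the obstructed kidney. Matrix genes rose in the fibrotic kidneys. Of 31 interstitial matrix genes tested, 25 rose and 0 fell, the same counts as adjusted over the list alone, with a median log2 change of 1.94 (camera adjusted p = 1.2e-09, and adjusted p = 0.24 with an estimated correlation). Col8a1, a short-chain collagen, rose by 4.03 ± 0.28 (SE) log2 units and Sparc, a collagen-binding matrix protein, by 2.42 ± 0.17. Col3a1, a fibrillar collagen, was not above background in healthy kidneys and was at least 7.83-fold higher in fibrotic ones (log2 level 8.29 ± 0.49, SD, n = 2; limma adjusted p = 1.5e-05). Col1a1 rose 18.4-fold, from 5.17 ± 0.85 (SD, n = 3) to 9.37 ± 0.49 (SD, n = 2; limma adjusted p = 0.00012), and was above background in 1 healthy kidney. Genes of collagen processing and crosslinking rose too, 16 higher and 1 lower of 22 (18 and 1 adjusted over the list alone, median 0.98, camera adjusted p = 3e-05, and adjusted p = 0.24 with an estimated correlation). The crosslinking enzyme Loxl1 rose by 2.78 ± 0.15 (SE), and Lox, another, at least 17.5-fold (27.9-fold without fibrotic kidney replicate 1 and 10.9-fold without replicate 2). Of 23 matrix proteases and inhibitors, 16 rose and 0 fell (17 and 0 adjusted over the list alone, median 1.47, camera adjusted p = 7.5e-06, and adjusted p = 0.24 with an estimated correlation). The gelatinase Mmp2 rose by 3.15 ± 0.22, its activator Mmp14 by 3.79 ± 0.24, and the lysosomal protease Ctss was at least 2.59-fold higher. Timp1, an inhibitor of these proteases, was at least 79.3-fold higher, with log2 levels of 9.51 and 13.75 in the obstructed kidneys (344-fold without replicate 1 of them and 18.3-fold without replicate 2).

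Genes of contractile fibroblasts and of TGF-beta signalling rose in the same kidneys. For the myofibroblast and smooth muscle list, 13 of 22 genes rose and 1 fell (15 and 1 adjusted over the list alone, median 1.17, camera adjusted p = 0.00053, and adjusted p = 0.32 with an estimated correlation). Acta2, smooth muscle actin, rose 4.60-fold from 10.24 ± 0.58 (SD, n = 3) to 12.44 ± 0.40 (SD, n = 2; limma adjusted p = 0.0015), Tpm1 by 1.67 ± 0.15 (SE) and Tagln, an actin-binding protein, at least 4.07-fold. Thy1, a surface marker of fibroblasts and of T cells, rose by 4.38 ± 0.47. In the TGF-beta list, 14 of 19 genes rose and 1 fell, also adjusted over the list alone (median 1.64, camera adjusted p = 0.00013, and adjusted p = 0.24 with an estimated correlation). Tgfb1 itself rose by 2.66 ± 0.31, and its targets Ccn2 and Tgfbi by 1.87 ± 0.18 and 3.03 ± 0.31. Ltbp3, which binds the latent ligand, rose by 2.06 ± 0.21, and Fn1, fibronectin, by 3.03 ± 0.34.

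Macrophage, MHC class II, chemokine, interferon and tubular injury lists rose as well. Of 28 macrophage and monocyte genes, 23 rose and 1 fell (24 and 1 adjusted over the list alone, median 2.39, camera adjusted p = 1.2e-09, and adjusted p = 0.24 with an estimated correlation). The mannose receptor Mrc1 rose by 3.36 ± 0.16, lysozyme Lyz1 by 3.37 ± 0.20 and the Fc receptor Fcgr3 by 4.26 ± 0.28. Fcrls, another myeloid surface protein, was at least 23.1-fold higher. Genes of dendritic cells and MHC class II rose, 12 higher and 0 lower of 17 (13 and 0 adjusted over the list alone, median 1.91, camera adjusted p = 1.2e-05, and adjusted p = 0.24 with an estimated correlation). H2-Ab1 rose by 2.46 ± 0.32, H2-DMa by 1.94 ± 0.25 and the costimulator Cd86 by 2.78 ± 0.27. Chemokines went 17 higher and 1 lower of 30 (17 and 2 adjusted over the list alone, median 2.21, camera adjusted p = 8.2e-05, and adjusted p = 0.24 with an estimated correlation). Ccl9 rose by 5.65 ± 0.33, Ccl5 by 4.46 ± 0.33 and Ccl2 at least 3.37-fold. Interferon response genes went 20 higher and 0 lower of 29 (22 and 0 adjusted over the list alone, median 1.39, camera adjusted p = 1.9e-07, and adjusted p = 0.24 with an estimated correlation). Irf7, Rtp4 and Ifi27 rose, Irf7 at least 4.15-fold, Rtp4 at least 1.46-fold and Ifi27 by 1.49 ± 0.16. The neutrophil list (4 higher and 0 lower of 15, 2 and 0 adjusted over the list alone, median 1.36, camera adjusted p = 0.14), the T and NK cell list (4 and 0 of 16, 3 and 0 adjusted over the list alone, median 0.36, camera adjusted p = 0.23) and the B and plasma cell list (1 and 2 of 11, also adjusted over the list alone, median -0.11, camera adjusted p = 0.54) did not pass. The neutrophil median was 0.10 in fibrotic kidney replicate 1 and 2.80 in replicate 2. The chemokine median was 1.16 without fibrotic kidney replicate 2 (camera adjusted p = 0.00018).

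Of 24 tubular injury genes, 19 rose and 1 fell, also adjusted over the list alone (median 2.54, camera adjusted p = 1.1e-08, and adjusted p = 0.24 with an estimated correlation). The adhesion molecules Vcam1 and Cd44 rose by 4.01 ± 0.16 and 4.21 ± 0.29, and the transcription factor Sox4 by 3.57 ± 0.23. Lcn2, which sequesters iron carriers and is a marker of tubular injury, rose 141-fold (limma adjusted p = 0.00014), with log2 levels of 11.30 and 14.83 in the obstructed kidneys and 5.92 ± 0.66 (SD, n = 3) in healthy ones (479-fold without fibrotic kidney replicate 1 and 41.5-fold without replicate 2). Krt20, a keratin of urothelium and injured tubule, was at least 24.4-fold higher, with levels of 8.59 and 11.27 in the obstructed kidneys (61.7-fold without replicate 1 of them and 9.64-fold without replicate 2). Socs3, a feedback inhibitor of cytokine signalling, rose by 5.34 ± 0.39 (SE). Havcr1, a tubular injury receptor, rose by 2.14 ± 0.67 (limma adjusted p = 0.029). That call was lost without fibrotic kidney replicate 2 (0.69, adjusted p = 0.289) and without healthy kidney replicate 1 (2.07, adjusted p = 0.0717) or 2 (2.06, adjusted p = 0.0716). Without fibrotic kidney replicate 1 the change was 3.58. Cell cycle genes rose, 22 higher and 0 lower of 33, also adjusted over the list alone (median 1.27, camera adjusted p = 1.3e-06, and adjusted p = 0.32 with an estimated correlation). The kinesin Kif22 rose by 2.68 ± 0.30, the mitotic factor Cdca8 at least 5.92-fold (9.53-fold without fibrotic kidney replicate 1 and 3.67-fold without replicate 2) and the replication helicase subunit Mcm6 by 2.54 ± 0.31.

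Metabolic and proximal tubule genes fell. Of 34 genes of fatty acid oxidation and peroxisomes, 20 fell and 0 rose (21 and 0 adjusted over the list alone, median -1.02, camera adjusted p = 2.1e-09, and adjusted p = 0.24 with an estimated correlation). Ppara, the nuclear receptor that drives this pathway, changed by -2.42 ± 0.30, and the peroxisomal enzymes Acox3 and Ehhadh by -2.12 ± 0.23 and -1.70 ± 0.21. Of 51 oxidative phosphorylation genes, 17 fell and 0 rose (16 and 0 adjusted over the list alone, median -0.34, camera adjusted p = 1e-05, and adjusted p = 0.53 with an estimated correlation, and 0.057 with fry). The ATP synthase subunit Atp5pb changed by -2.00 ± 0.17, cytochrome c, Cycs, by -1.38 ± 0.20 and the complex I subunit Ndufs4 by -0.63 ± 0.14. Of 50 proximal tubule genes, 22 fell and 4 rose (23 and 4 adjusted over the list alone, median -1.14, camera adjusted p = 1.3e-06, and adjusted p = 0.33 with an estimated correlation). Acsm3, a medium-chain acyl-CoA ligase, fell 182-fold, from 13.09 ± 0.10 (SD, n = 3) to 5.58 ± 0.24 (SD, n = 2; limma adjusted p = 6.9e-06), and the amino acid transporter Slc7a13 was at least 5.88-fold lower, whereas the fatty acid hydroxylase Cyp4a14 rose by 4.38 ± 0.31 (SE). Cyp4a14 is also among the female-biased kidney genes, and sex-linked transcripts differed between these kidneys, as given below. Umod, the main urinary protein of the thick ascending limb, stood at 14.50 ± 0.12 (SD, n = 3) and 14.47 ± 0.12 (SD, n = 2; limma adjusted p = 0.99). Of 11 erythroid genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone, median -0.86, camera adjusted p = 0.0006, and adjusted p = 0.24 with an estimated correlation). The sizes of these list changes depended on the obstructed kidneys, at n = 2. Without replicate 1 of them the medians were -1.91 for the proximal tubule, -0.63 for oxidative phosphorylation and -0.55 for the erythroid list, and without replicate 2 they were -0.61, -0.07 and -1.39, with -0.54 for fatty acid oxidation. Each of these lists still passed in camera without either array.

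Sex-linked transcripts moved with this comparison. Xist, the RNA of the inactive X chromosome, was not above background in the 3 healthy kidneys (4.41 to 4.74) and stood at 10.83 and 10.56 in the obstructed ones, at least 41.5-fold higher. The Y-linked Eif2s3y stood at 9.06 to 9.41 in healthy kidneys and at 4.42 and 4.40 in obstructed ones, at least 17.7-fold lower (limma adjusted p = 0.012; 0.0589 without fibrotic kidney replicate 2), although all mice are labelled female. Of 14 androgen-dependent kidney genes, a list written after the data were seen, 13 fell and 0 rose (14 and 0 adjusted over the list alone, median -4.45, camera adjusted p = 1.3e-10, and adjusted p = 0.026 with an estimated correlation). Of the 14, 5 are among the largest falls, which were seen before the list was written, so this test is not independent evidence. Of 4 female-biased kidney genes, also written after, 2 rose and 2 fell, also adjusted over the list alone (median 0.43, camera adjusted p = 0.96): Cyp4a14 and Slc7a12 rose by 4.38 and 2.36, and Akr1c18 and Slc22a7 changed by -1.50 and -1.90. Several of the largest falls belong to families known for sex-biased expression in rodent kidney: the transporters Slc22a30 (-6.56 ± 0.67, SE) and Slc22a28 (-6.22 ± 0.63), the cytochromes Cyp2d12 (-5.26 ± 0.24) and Cyp2j13 (-4.79 ± 0.26), the urinary protein Mup2 (-6.72 ± 2.16, adjusted p = 0.032) and the glucuronosyltransferase Ugt2b36 (-4.97 ± 1.61, adjusted p = 0.033). Probes of these families can cross-hybridise between close relatives. Mup2 is also an abundant liver transcript, and liver transcripts were also found in the healthy kidneys, with changes not past the threshold in the fit over all arrays. Apoa1 stood at 8.62, 7.58 and 6.79 there and at 4.98 and 4.65 in the obstructed ones (limma adjusted p = 0.35, and 0.0116 with only the kidney arrays), and Mup3 at 10.05, 9.26 and 7.94 and at 4.41 and 4.39 (limma adjusted p = 0.14, and 0.0041 with only the kidney arrays). The fit over all arrays takes each gene's spread from all 4 groups, and healthy lung replicate 3 carried liver transcripts. Of 21 liver genes, a list written after the data were seen, 1 fell and 0 rose (0 and 0 adjusted over the list alone, median -0.84, camera adjusted p = 0.16). The falls of Mup2 and Ugt2b36 stayed large in the settings given next, though their calls were lost. Their SEs, 2.16 and 1.61, rest on the spread shared by all groups, and Mup2 varied widely between the healthy lungs. The Mup2 call was lost without healthy kidney replicate 1 (-6.16, adjusted p = 0.0862) or 2 (-6.76, 0.0664) and without fibrotic kidney replicate 1 (-6.06, 0.133) or 2 (-7.37, 0.0859). The Ugt2b36 call was lost without healthy kidney replicate 1 (-4.97, adjusted p = 0.0707), 2 (-4.96, 0.0704) or 3 (-4.98, 0.0667) and without fibrotic kidney replicate 1 (-5.24, 0.0877) or 2 (-4.70, 0.137).

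Lung transcripts were also found in the obstructed kidneys. Scgb1a1, the secretoglobin of airway club cells, was not above background in healthy kidneys and stood at 12.48 and 11.35 in the obstructed ones, at least 96.9-fold higher. The surfactant proteins Sftpd and Sftpc were at least 14.1-fold and 8.99-fold higher, with Sftpd at 9.52 and 8.76 and Sftpc at 9.22 and 7.75 (Sftpc 5.39-fold without fibrotic kidney replicate 1 and 14.98-fold without replicate 2). Of 25 alveolar type 2 cell genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.32, camera adjusted p = 0.069; fry adjusted p = 8.8e-05, and adjusted p = 0.33 with an estimated correlation). Camera called this list without healthy kidney replicate 2 (median 0.37, adjusted p = 0.049) and without fibrotic kidney replicate 2 (0.26, 0.037). Of 21 club cell genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone, median 0.20, camera adjusted p = 0.9). The basal keratin Krt5 was at least 1.73-fold higher, and the cytochrome Cyp4b1 fell by 4.70 ± 0.23 log2 units.

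In all, 4987 of the 12865 genes (38.8%) passed the threshold between fibrotic and healthy kidney, 2982 higher and 2005 lower, and 1629 and 1005 of them by at least 2-fold. Of the 41 lists, 21 passed in camera, 17 up and 4 down. With an estimated correlation 0 of these 41 lists passed in this or any other contrast, so their camera calls rest on the preset correlation. In kidney 6 lists had an unadjusted p under 0.05 with an estimated correlation, and fry called 26. The share of higher genes among the calls depended on the scaling of the arrays, at 59.8% as reported, 77.1% with a common median and 32.1% in the authors' processed intensities. The median change of all genes moved from 0.10 to 0.27 and -0.24 between these scalings, and relative to it 99.9% of the called genes kept their sign in either.

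**Figure D1:**
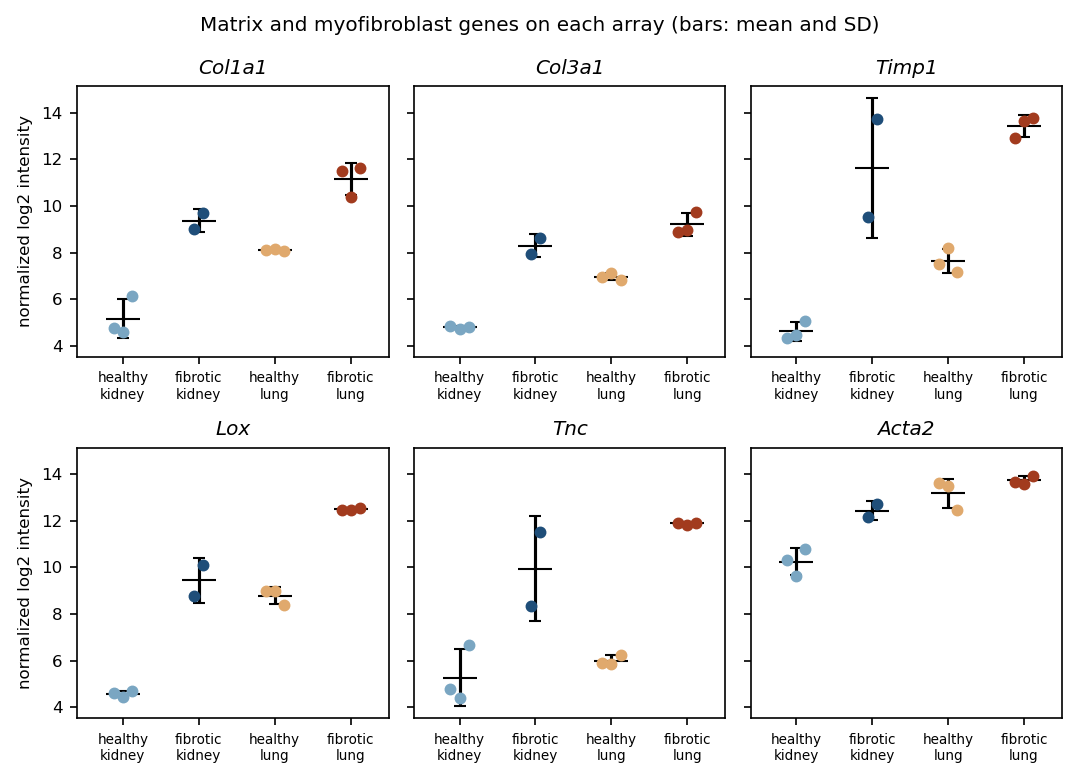
Log2 level of Col1a1, Col3a1, Timp1, Lox, Tnc and Acta2 on each array (points) by group, with the group mean and SD as bars. Col1a1 means rise from 5.17 to 9.37 in kidney and from 8.10 to 11.16 in lung, and Acta2 means from 10.24 to 12.44 and from 13.19 to 13.74.

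The second comparison asked what changed in the bleomycin-treated lung. Cell cycle and macrophage genes rose there. Of 33 cell cycle genes, 26 rose and 1 fell (27 and 1 adjusted over the list alone, median 1.34, camera adjusted p = 6.8e-09, and adjusted p = 0.33 with an estimated correlation). The nucleotide synthesis enzymes Tk1 and Tyms rose by 2.07 ± 0.22 (SE) and 2.23 ± 0.25, and the mitotic kinase Cdk1 by 3.27 ± 0.37. Of 28 macrophage and monocyte genes, 20 rose and 0 fell, also adjusted over the list alone (median 1.78, camera adjusted p = 1.1e-08, and adjusted p = 0.15 with an estimated correlation). The Fc receptor Fcgr2b rose by 3.57 ± 0.20, Mrc1 by 2.25 ± 0.14 and the scavenger receptor Msr1 by 3.22 ± 0.23. Of 14 genes of alternatively activated macrophages, 12 rose and 0 fell (13 and 0 adjusted over the list alone, median 2.25, camera adjusted p = 1.7e-06, and adjusted p = 0.15 with an estimated correlation). Fn1 rose by 3.07 ± 0.31 and the secreted ribonuclease Rnase2a by 5.01 ± 0.57. Chemokines went 15 higher and 4 lower of 30, also adjusted over the list alone (median 1.13, camera adjusted p = 0.0046, and adjusted p = 0.38 with an estimated correlation). The monocyte attractants Ccl7 and Ccl2 rose, Ccl7 by 5.39 ± 0.30 and Ccl2 at least 14.1-fold, and Cx3cl1 fell by 1.99 ± 0.14. The tubular injury list rose in lung as well, 15 higher and 1 lower of 24 (16 and 1 adjusted over the list alone, median 1.14, camera adjusted p = 2.5e-05, and adjusted p = 0.37 with an estimated correlation), with Lcn2 from 10.06 ± 0.74 to 13.57 ± 0.34 (SD, n = 3 each; limma adjusted p = 0.0047) and Cd44 higher by 1.69 ± 0.26. Without fibrotic lung replicate 3 the chemokine median was 0.74 (camera adjusted p = 0.022). The secreted proteins Wfdc17 and Saa3 rose by 5.91 ± 0.33 and 4.98 ± 1.03, and the cystatin family members Stfa1 and Stfa2, whose probes can cross-hybridise, by 5.81 ± 0.85 and 5.35 ± 0.48.

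Matrix genes rose in the fibrotic lung, with 19 higher and 3 lower of the 31 interstitial matrix genes (20 and 3 adjusted over the list alone, median 0.90, camera adjusted p = 1.1e-05, and adjusted p = 0.33 with an estimated correlation). Eln, elastin, rose by 4.38 ± 0.27 (SE), Col5a2 by 3.11 ± 0.20, and the proteoglycan Vcan was at least 3.84-fold higher. Col1a1 rose 8.35-fold, from 8.10 ± 0.05 to 11.16 ± 0.69 (SD, n = 3 each; limma adjusted p = 0.00048), and Col3a1 4.73-fold, from 6.97 ± 0.16 to 9.21 ± 0.48 (SD, n = 3 each; limma adjusted p = 0.00015). Matrix proteases and inhibitors went 14 higher and 0 lower of 23 (15 and 1 adjusted over the list alone, median 1.40, camera adjusted p = 1.4e-05, and adjusted p = 0.15 with an estimated correlation). Mmp14 rose by 2.18 ± 0.22, the collagenase Mmp13 by 3.54 ± 0.37, the stromelysin Mmp10 at least 12.1-fold and Timp1 by 5.82 ± 0.82. Of 22 collagen processing genes, 9 rose and 2 fell, also adjusted over the list alone (median 0.40, camera adjusted p = 0.016, and adjusted p = 0.41 with an estimated correlation). Lox rose by 3.72 ± 0.30 and Loxl1 by 1.62 ± 0.14, and the procollagen proteinase enhancer Pcolce2 fell by 2.16 ± 0.14. The myofibroblast list did not pass (5 higher and 3 lower of 22, also adjusted over the list alone, camera adjusted p = 0.47, and adjusted p = 0.8 with an estimated correlation), nor did the TGF-beta list (5 higher and 2 lower of 19, also adjusted over the list alone, camera adjusted p = 0.41, and adjusted p = 0.8 with an estimated correlation). The changes of Acta2 (0.55 ± 0.34, limma adjusted p = 0.24) and Tgfb1 (-0.10 ± 0.28, limma adjusted p = 0.82) were not past the threshold. Acta2 was past it with a common median (0.95, adjusted p = 0.0472), in the authors' processed intensities (1.13, 0.0209) and in another of its probes (1.98, 0.0010).

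Vessel, lymphocyte and antigen presentation genes fell in the fibrotic lung. Of 31 endothelial genes, 18 fell and 0 rose (20 and 0 adjusted over the list alone, median -0.71, camera adjusted p = 4.4e-06, and adjusted p = 0.15 with an estimated correlation). The TGF-beta co-receptor Eng changed by -1.40 ± 0.13 (SE), the receptor kinase Tie1 by -1.63 ± 0.17 and the apelin receptor Aplnr by -2.04 ± 0.23. Of 11 B and plasma cell genes, 9 fell and 0 rose, also adjusted over the list alone (median -1.54, camera adjusted p = 1.4e-05, and adjusted p = 0.15 with an estimated correlation). The kinase Blk changed by -2.05 ± 0.17, the antigen receptor chain Cd79b by -2.60 ± 0.28 and Cd72 by -1.72 ± 0.19. Of 16 T and NK cell genes, 10 fell and 0 rose (11 and 0 adjusted over the list alone, median -1.50, camera adjusted p = 3e-05, and adjusted p = 0.33 with an estimated correlation). Perforin, Prf1, changed by -1.94 ± 0.16, Cd2 by -1.55 ± 0.11 and Klrd1 by -1.97 ± 0.22. Of 17 genes of dendritic cells and MHC class II, 10 fell and 0 rose (11 and 0 adjusted over the list alone, median -1.60, camera adjusted p = 0.00021, and adjusted p = 0.34 with an estimated correlation). H2-Ab1 changed by -2.28 ± 0.29, H2-Eb1 by -2.59 ± 0.34 and the invariant chain Cd74 by -1.90 ± 0.25.

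Red cell transcripts made up many of the largest falls in lung. Of 11 erythroid genes, 7 fell and 0 rose, also adjusted over the list alone (median -4.65, camera adjusted p = 2.5e-05, and adjusted p = 0.15 with an estimated correlation). The haemoglobin genes Hbb-b2, Hbb-bs, Hbb-bt and Hba-a1 changed by -6.31 ± 0.20 (SE), -5.25 ± 0.30, -4.86 ± 0.30 and -5.14 ± 0.30, with probes that can cross-hybridise among the beta chains. Alas2, the erythroid enzyme of haem synthesis, changed by -5.50 ± 0.34, and the red cell anion exchanger Slc4a1 was at least 20.4-fold lower. The oxidase Aox3 changed by -4.39 ± 0.29. Adipocyte genes went 0 higher and 6 lower of 14, also adjusted over the list alone (median -1.08, camera adjusted p = 0.016, and adjusted p = 0.55 with an estimated correlation). The adipocyte call was lost without healthy lung replicate 2 (median -0.69, camera adjusted p = 0.11). Cidec changed by -3.71 ± 0.63 and Lep by -1.65 ± 0.37, and Thrsp was at least 13.7-fold lower (35.2-fold without healthy lung replicate 1 and 7.89-fold without replicate 3). The fat hormone Adipoq stood at 7.75, 10.49 and 10.34 in healthy lungs and 4.94, 5.22 and 7.42 in fibrotic ones. Of 25 alveolar type 2 cell genes, 8 fell and 2 rose, also adjusted over the list alone (median -0.41, camera adjusted p = 0.035, and adjusted p = 0.34 with an estimated correlation). Hc changed by -3.81 ± 0.35 and Lgi3 by -2.48 ± 0.27, whereas the protease Ctsh rose by 1.82 ± 0.15. The call of this list was lost without healthy lung replicate 3 (median -0.44, camera adjusted p = 0.057) or fibrotic lung replicate 2 (-0.32, 0.081). In the authors' processed intensities, where the median change of all genes in lung was 0.48, the medians of the alveolar type 2 and fatty acid oxidation lists were above 0, and relative to that shift no list median turned. Sftpc (-0.47 ± 0.29, limma adjusted p = 0.24), the alveolar type 1 receptor Ager (-0.64 ± 0.31, 0.13) and Scgb1a1 (0.41 ± 0.24, 0.21) were not past the threshold, though each was under other settings: Sftpc (adjusted p = 0.0212) and Ager (0.0117) with only the lung arrays, and Scgb1a1 with a common median (0.0326).

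In all, 4863 genes (37.8%) passed between fibrotic and healthy lung, 2437 higher and 2426 lower, and 1054 and 1016 of them by at least 2-fold. Of the lists, 20 passed in camera, 12 up and 8 down, and 24 in fry. The share of higher genes among the calls was 50.1% as reported, 75.9% with a common median and 88.0% in the authors' processed intensities. Some lung arrays held transcripts of other tissues or stood apart in sex-linked ones: healthy lung replicate 3 had the liver transcripts Apoa1 at 13.94 and Ttr at 13.98, fibrotic lung replicate 1 had the kidney transcripts Umod at 9.19 and Slc34a1 at 7.70, and fibrotic lung replicate 3 had Xist at 9.03 and Eif2s3y at 4.44. Lower levels above background were found on other arrays and for other transcripts too, with Xist at 5.61 in fibrotic lung replicate 1, Umod at 5.74 in fibrotic lung replicate 2 and Slc34a1 at 6.62 in healthy lung replicate 1. Without healthy lung replicate 3 and fibrotic lung replicates 1 and 3 together, a setting chosen after the data were seen, 3114 genes passed, 2705 of them among those reported and in the same direction. The calls of Lcn2 (3.45, adjusted p = 0.0975), Lep (-1.73, adjusted p = 0.0955), Thrsp (-3.16, adjusted p = 0.177) and Saa3 (5.16, adjusted p = 0.0774) were lost in that setting, as was that of the collagen processing list (median 0.34, camera adjusted p = 0.081).

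**Figure D2:**
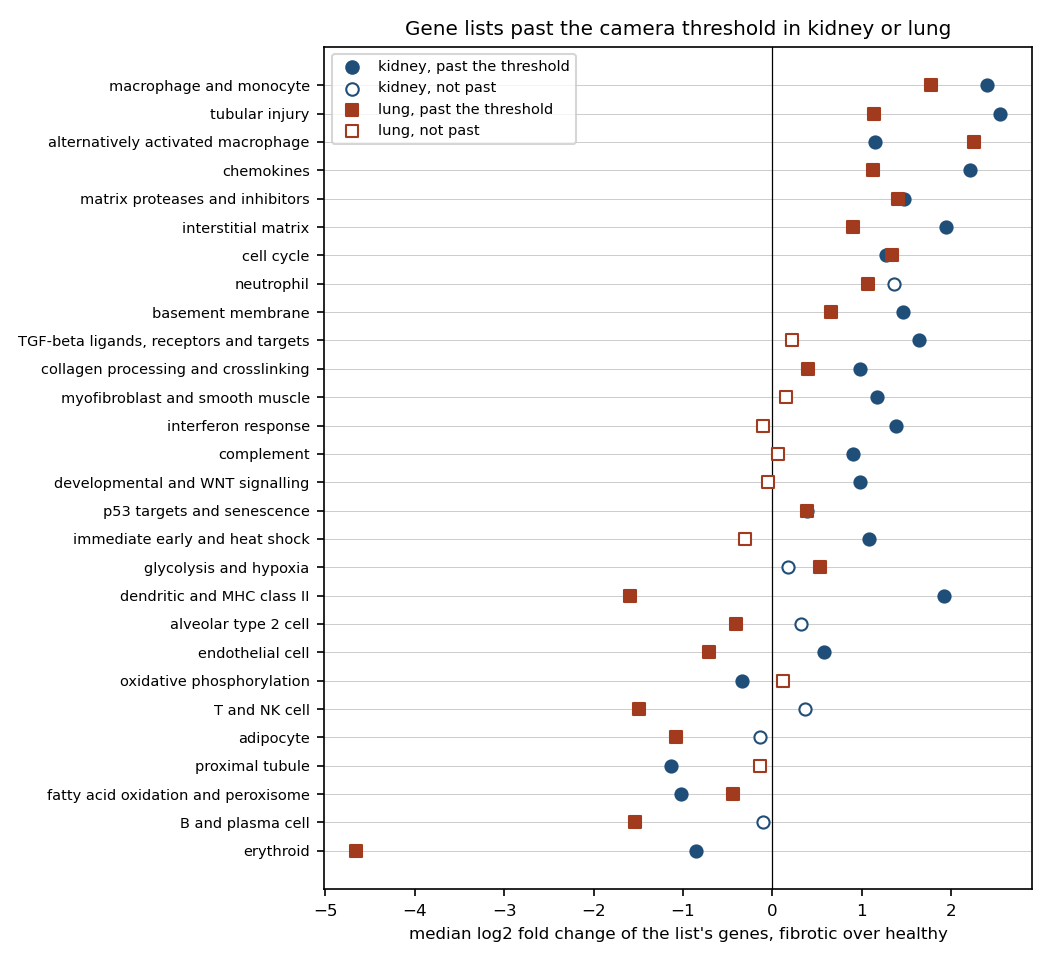
Median log2 change of the 28 gene lists past camera in kidney or lung, with filled points where the list passed in that organ. The largest medians are 2.54 for tubular injury in kidney and -4.65 for the erythroid list in lung.

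Changes shared by both fibrotic organs were counted next. Of the 2144 genes called in both organs, 1067 (49.8%) went the same way. The 710 genes higher in both were more than the 564.9 that independent lists would share (odds ratio 1.48, Fisher's exact test p = 3.3e-14), and the 357 genes lower in both were close to the 378 of independent lists (odds ratio 0.920, Fisher's exact test p = 0.203). The 628 genes higher in kidney and lower in lung, and the 449 lower in kidney and higher in lung, compare with 562 and 380. Genes called in opposite directions were thus also more than independent lists would share. Both contrasts come from the same fit and share each gene's estimate of spread, and genes are not independent of each other. The Fisher's exact tests are therefore descriptive. With a common median 1610 genes were higher in both and 131 lower, and in the authors' processed intensities 940 and 216. The odds ratio for rises was 1.57 and 1.46 there (Fisher's exact test p = 1.3e-29 and 3.6e-13), and for falls 1.06 and 0.901 (p = 0.552 and 0.213). Without background correction it was 1.60 for rises (p = 4.5e-20) and 0.852 for falls (Fisher's exact test p = 0.0113). Across genes, which are not independent replicates, the changes correlated at Pearson r = 0.165 and Spearman rho = 0.0545. The kidney and lung changes use different arrays, though the healthy organs came from the same mice.

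The 8 largest shared rises are named by the smaller of both changes. Timp1 and Lox rose in both, as did Tnc, the matrix protein tenascin C (4.67 ± 0.82, SE, in kidney and 5.89 ± 0.74 in lung). So did the aggrecan protease Adamts4 (at least 21.4-fold and 19.5-fold), the tight junction protein Cldn4 (4.18 ± 0.50 and 4.68 ± 0.45), the membrane protein Ms4a6d (4.57 ± 0.36 and 3.60 ± 0.32) and the chemokines Ccl7 (at least 8.97-fold in kidney and 5.39 ± 0.30 in lung) and Ccl12 (at least 12.1-fold and 3.56 ± 0.34). Without fibrotic kidney replicate 2 the kidney change of Tnc was 3.08, and Adamts4 and Ccl7 were at least 5.65-fold and 5.48-fold higher in kidney, against 80.8-fold and 14.7-fold without replicate 1. The 8 largest shared falls included the carboxylesterases Ces1f (-4.52 ± 0.41 in kidney and -3.83 ± 0.37 in lung) and Ces1e (-2.76 ± 0.65 and -2.51 ± 0.58), the cytochromes Cyp2e1 (-3.35 ± 0.98 and -4.81 ± 0.88) and Cyp2a5 (-3.51 ± 0.57 and -2.82 ± 0.51), and the monooxygenase Fmo5 (-3.32 ± 0.64 and -2.58 ± 0.57). The epoxide hydrolase Ephx2 (-2.39 ± 0.81 and -2.19 ± 0.72), the sulfate transporter Slc13a4 (-2.15 ± 0.34 and -2.21 ± 0.30) and the regulator Gchfr (-1.94 ± 0.46 and -1.90 ± 0.41) fell too. Probes of the Ces1 and Cyp2 families can cross-hybridise. The healthy kidneys also held liver transcripts, and Cyp2e1 is among the listed androgen-dependent kidney genes. Neither liver RNA nor sex was tested as a source of these shared falls.

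Several of these falls lay near the threshold and lost the call when single arrays were left out. In kidney, Cyp2e1 lost its call without healthy kidney replicate 1 (-3.33, adjusted p = 0.0502) or 2 (-3.30, 0.0515) or fibrotic kidney replicate 2 (-2.86, 0.130), and Gchfr without fibrotic kidney replicate 2 (-1.45, 0.0766). Ces1e changed by -4.17 without fibrotic kidney replicate 1 and by -1.36 without replicate 2. Ephx2 lost its call in kidney without healthy kidney replicate 1 (-2.52, 0.0670), 2 (-2.24, 0.0951) or 3 (-2.43, 0.0717) or fibrotic kidney replicate 2 (-1.77, 0.236). In lung, Ephx2 lost its call without healthy lung replicate 2 (-2.27, 0.0682) or 3 (-1.24, 0.0612) or without fibrotic lung replicate 1 (-2.14, 0.0876), 2 (-2.07, 0.102) or 3 (-2.37, 0.0594). Healthy lung replicate 3 carried liver transcripts, and without it and fibrotic lung replicates 1 and 3 the lung calls of Ces1e (-2.16, adjusted p = 0.136), Ephx2 (-1.50, 0.166) and Fmo5 (-2.10, 0.0559) were lost and 556 genes went the same way in both organs.

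**Figure D3:**
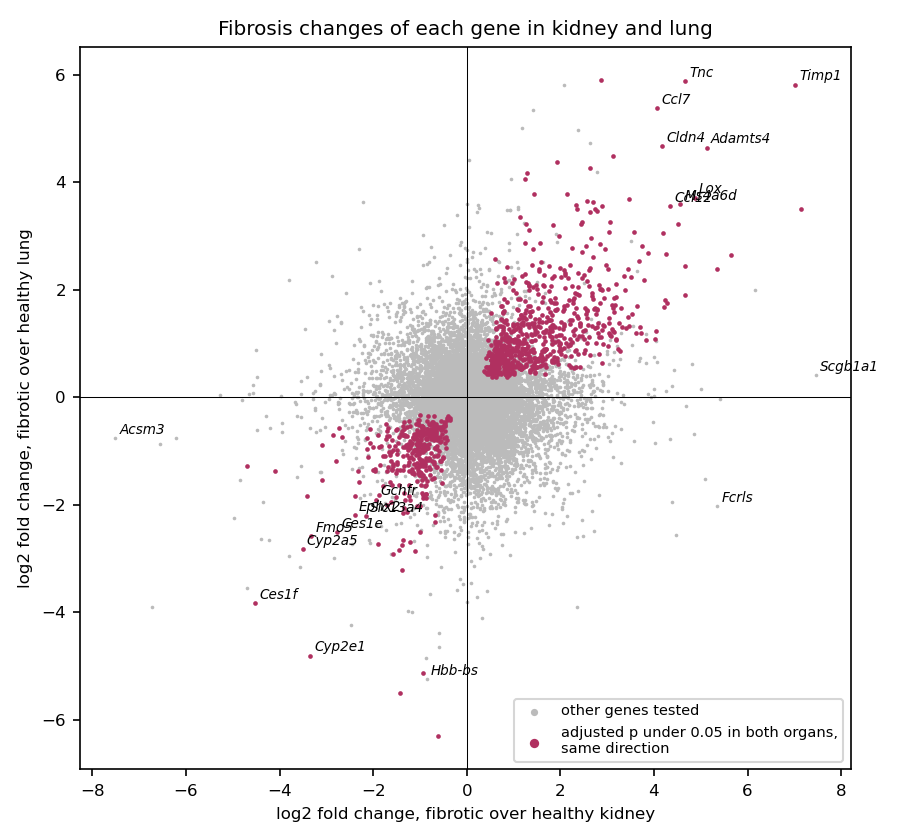
Log2 change in fibrotic against healthy kidney (x axis) and lung (y axis) for each of the 12865 genes, with genes called the same way in both organs coloured. The 710 genes higher in both and the 357 lower in both lie in opposite corners, and r across genes is 0.165.

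The difference between the organs' responses was tested directly. Genes of dendritic cells and MHC class II rose in kidney and fell in lung as a list, and 15 of its 17 had a higher change in kidney and 0 a lower one (16 and 0 adjusted over the list alone, median difference 2.50, camera adjusted p = 8.7e-07, and adjusted p = 0.47 with an estimated correlation). The difference was 4.75 ± 0.43 (SE) for H2-Ab1, 5.08 ± 0.51 for H2-Eb1 and 3.98 ± 0.37 for Cd74. Interferon response genes had higher changes in kidney, 22 of 29, and 0 lower ones (24 and 0 adjusted over the list alone, median difference 1.74, camera adjusted p = 1.1e-05, and adjusted p = 0.58 with an estimated correlation). Ifi27 differed by 2.27 ± 0.21, Irf7 by 2.42 ± 0.26 and Irf1 by 2.48 ± 0.28. In lung alone this list did not pass (2 higher and 5 lower of 29, 1 and 4 adjusted over the list alone, camera adjusted p = 0.41, and adjusted p = 0.8 with an estimated correlation). Endothelial genes had higher changes in kidney, 19 of 31, and 1 lower one (22 and 1 adjusted over the list alone, median difference 1.28, camera adjusted p = 4e-05, and adjusted p = 0.47 with an estimated correlation). Eng differed by 2.36 ± 0.20 and Aplnr by 4.07 ± 0.35. T and NK cell genes differed likewise, 10 higher and 0 lower of 16 (11 and 0 adjusted over the list alone, median difference 1.70, camera adjusted p = 0.0012, and adjusted p = 0.62 with an estimated correlation). Prf1 differed by 2.47 ± 0.24, Cd2 by 1.67 ± 0.17 and Klrd1 by 3.19 ± 0.33. The median of this list was 0.36 in kidney, where it did not pass (camera adjusted p = 0.23), and -1.50 in lung.

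TGF-beta and myofibroblast genes had higher changes in kidney than in lung. The TGF-beta list went 11 higher and 1 lower of 19 (12 and 1 adjusted over the list alone, median difference 1.21, camera adjusted p = 0.013, and adjusted p = 0.62 with an estimated correlation). Ltbp3 differed by 2.55 ± 0.28 (SE), Tgfb3 by 2.20 ± 0.28 and the matricellular protein Thbs1 by -3.24 ± 0.46. The myofibroblast list went 9 higher and 1 lower of 22 (10 and 1 adjusted over the list alone, median difference 1.14, camera adjusted p = 0.029, and adjusted p = 0.72 with an estimated correlation, and 0.085 with camera on values without background correction). Thy1 differed by 6.32 ± 0.64, the integrin Itga8 by 2.53 ± 0.32 and the calcium-binding S100a4 by -2.57 ± 0.38. Without fibrotic kidney replicate 2 the TGF-beta list (median difference 0.77, camera adjusted p = 0.065) and the myofibroblast list (0.81, 0.12) lost the call, and the latter also without fibrotic lung replicate 2 (0.97, 0.056). Oxidative phosphorylation genes had lower changes in kidney, 19 of 51, and 1 higher one, also adjusted over the list alone (median difference -0.49, camera adjusted p = 4.8e-05, and adjusted p = 0.72 with an estimated correlation, and 0.054 with fry). Atp5pb differed by -3.14 ± 0.23. The median difference of this list was -0.18 without fibrotic kidney replicate 2 (camera adjusted p = 0.030). In lung alone 8 rose and 1 fell of 51 (8 and 0 adjusted over the list alone, camera adjusted p = 0.11, and adjusted p = 0.8 with an estimated correlation), and camera called the list there without healthy lung replicate 2 (median 0.20, adjusted p = 0.014).

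The largest single differences included Fcrls (7.38 ± 0.32, SE), Scgb1a1 (7.04 ± 0.36), Ccl5 (7.02 ± 0.45) and the protease inhibitor Serpina10 (6.62 ± 1.53) on the side of kidney. Of the genes named here for the difference, Fcrls, Scgb1a1, Irf7, Klrd1, Cd2, Tgfb3, Thbs1 and Itga8 were not above background in healthy kidney, Cd2 not in fibrotic kidney either, and Slc22a30 not in fibrotic lung, so their differences are fitted values and no bounds. On the other side were Acsm3 (-6.74 ± 0.64), the glucuronosyltransferase Ugt1a7c (-5.98 ± 0.36), the zinc transporter Slc39a8 (-5.84 ± 0.60), the sterol enzyme Nsdhl (-5.73 ± 0.40) and Slc22a30 (-5.69 ± 0.89). In kidney, sex by Xist and the Y-linked transcripts coincided with obstruction, so these differences can also hold a difference in sex. Of 14 androgen-dependent kidney genes, 10 had a lower change in kidney and 0 a higher one, also adjusted over the list alone. Their median difference was -2.92 (camera adjusted p = 1.5e-06, and adjusted p = 0.089 with an estimated correlation). That list was written after the data were seen, so this is not independent evidence. Ccl5 went from 5.42 ± 0.04 (SD, n = 3) to 9.88 ± 0.58 (SD, n = 2) in kidney and from 8.61 ± 0.51 to 6.05 ± 0.41 (SD, n = 3 each) in lung. Nsdhl went from 9.53 ± 0.33 (SD, n = 3) to 6.32 ± 0.06 (SD, n = 2) in kidney and from 5.66 ± 0.49 to 8.18 ± 0.34 (SD, n = 3 each) in lung. The change differed for 5150 genes (40.0%), 3071 with the higher change in kidney and 2079 in lung, and 15 lists passed in camera, 12 up and 3 down. The share with the higher change in kidney was 59.6% as reported, 55.7% with a common median and 14.3% in the authors' processed intensities, in which the median difference of all genes was -0.77. Relative to the shifts of these scalings, 99.9% and 99.8% of the called genes kept their sign. The alveolar type 2 list, with a median difference of 0.90 (13 higher and 1 lower of 25, also adjusted over the list alone, camera adjusted p = 0.0067, and adjusted p = 0.47 with an estimated correlation), turned its sign in the authors' processed intensities and not relative to that shift.

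The healthy organs were compared last. Nephron and mitochondrial genes were higher in kidney. Of 50 proximal tubule genes, 46 were higher and 0 lower (46 and 1 adjusted over the list alone, median 4.86, camera adjusted p = 2.5e-17, and adjusted p = 0.26 with an estimated correlation). The organic ion transporters Slc22a6, Slc22a19 and Slc22a2 were at least 336-fold, 56.5-fold and 46.4-fold higher. Of 37 genes of the loop of Henle, distal tubule and collecting duct, 31 were higher and 4 lower, also adjusted over the list alone (median 3.48, camera adjusted p = 2.5e-09, and adjusted p = 0.26 with an estimated correlation). The water channel Aqp2 was at least 84.8-fold higher, the claudin Cldn16 at least 21.2-fold and Fxyd4 by 5.75 ± 0.21 (SE) log2 units. Of 51 oxidative phosphorylation genes, 49 were higher and 0 lower, also adjusted over the list alone (median 1.26, camera adjusted p = 2.6e-13, and adjusted p = 0.28 with an estimated correlation). Atp5pb was higher by 2.47 ± 0.15, Cyc1 by 1.98 ± 0.14 and Ndufs4 by 1.58 ± 0.12. The largest differences were Umod (at least 737-fold), Dnase1 (at least 613-fold), the kallikrein Klk1b27 (at least 561-fold, with relatives that its probe can take up), the phosphate transporter Slc34a1 (9.75 ± 0.82) and the androgen-regulated Kap (9.37 ± 0.35).

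Lung cell genes were higher in lung. Of 25 alveolar type 2 cell genes, 19 were higher in lung and 3 in kidney, also adjusted over the list alone (median -4.48, camera adjusted p = 9.5e-07, and adjusted p = 0.15 with an estimated correlation). In lung Sftpd was at least 646-fold, Sftpb at least 181-fold and the chemokine Cxcl15 at least 163-fold higher. Of 22 alveolar type 1 cell genes, 18 were higher in lung and 2 in kidney, also adjusted over the list alone (median -3.37, camera adjusted p = 2e-07, and adjusted p = 0.19 with an estimated correlation). Spock2 was at least 41.9-fold higher in lung, and Emp2 and caveolin, Cav1, differed by -5.97 ± 0.16 (SE) and -4.12 ± 0.13. Of 31 endothelial genes, 25 were higher in lung and 2 in kidney, also adjusted over the list alone (median -2.93, camera adjusted p = 2.5e-09, and adjusted p = 0.15 with an estimated correlation). Tmem100 differed by -7.01 ± 0.24, the cadherin Cdh5 by -4.99 ± 0.21 and Cldn5 by -4.91 ± 0.20. Interstitial matrix genes were higher in lung, 22 of 31, and 0 in kidney, also adjusted over the list alone (median -2.16, camera adjusted p = 1.1e-05, and adjusted p = 0.26 with an estimated correlation). Sparc differed by -3.25 ± 0.15, Col6a1 by -3.65 ± 0.17 and Mfap2 by -4.30 ± 0.24. Macrophage genes were higher in lung, 20 of 28, and 1 in kidney, also adjusted over the list alone (median -1.64, camera adjusted p = 4e-05, and adjusted p = 0.26 with an estimated correlation). The lysozymes Lyz1 and Lyz2 differed by -4.48 ± 0.17 and -5.07 ± 0.23. Scgb1a1 was at least 618-fold and Sftpc at least 429-fold higher in lung, with Chil1 at -8.45 ± 0.42 and the club cell cytochrome Cyp2f2 at -8.42 ± 0.28.

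Muscle genes, 25 of 29, were higher in the lung samples and 0 in the kidney samples, also adjusted over the list alone (median -3.89, camera adjusted p = 0.00082, and adjusted p = 0.52 with an estimated correlation). Cardiac actin, Actc1, was at least 54.0-fold (30.9-fold without healthy lung replicate 2 and 117-fold without replicate 3) and the troponin Tnnt1 at least 4.94-fold higher in lung, and Cox6a2 differed by -5.05 ± 0.69 (SE). The atrial and ventricular myosin Myh6 varied between healthy lungs, at 12.09, 13.01 and 6.26, and without healthy lung replicate 2 the muscle median was -2.54. In all, 7928 genes (61.6%) passed between the healthy organs, 3623 higher in kidney and 4305 higher in lung, and 2039 and 2667 of them by at least 2-fold. Of the lists, 30 passed in camera, 5 up and 25 down in kidney against lung. The share higher in kidney was 45.7% as reported and 67.6% in the authors' processed intensities, where the median of all genes moved from -0.09 to 0.40; relative to that shift 99.8% of the called genes kept their sign.

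**Figure D4:**
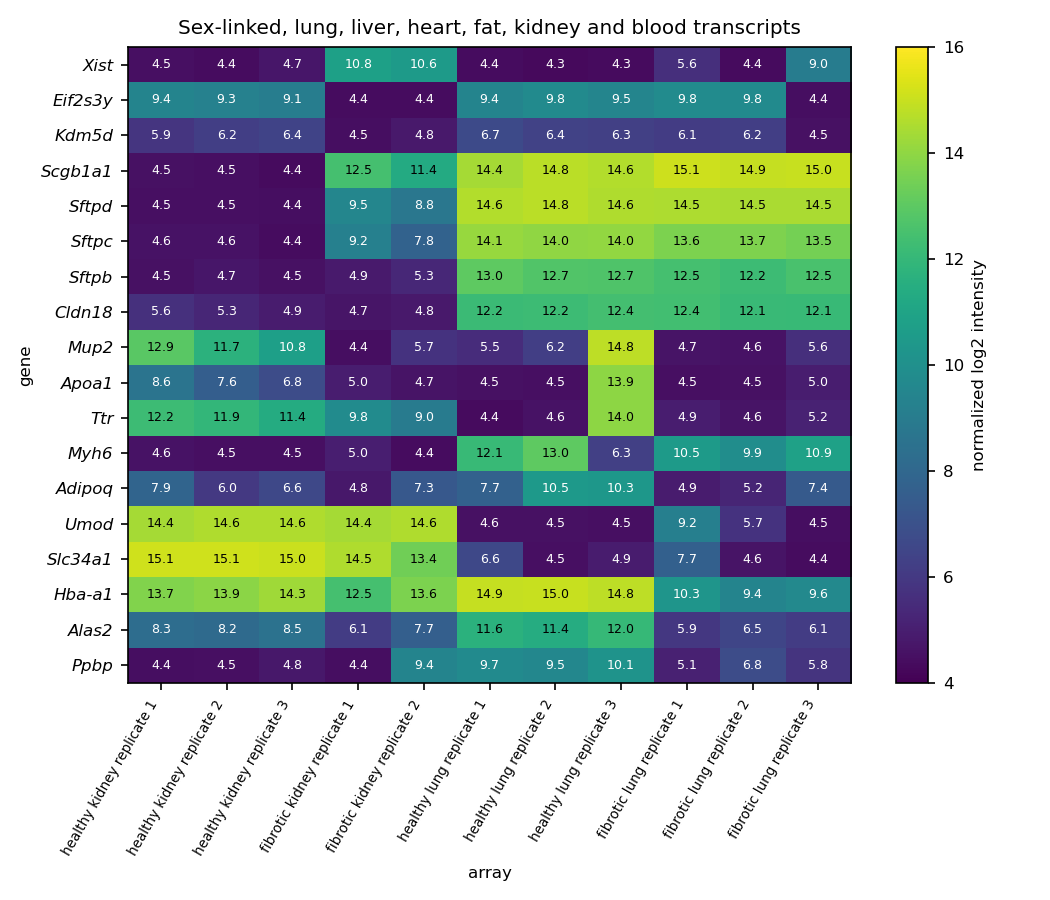
Log2 level of sex-linked transcripts and of transcripts typical of lung, liver, heart, fat, kidney, red cells and platelets on each of the 11 arrays, as colour. Xist is at 10.83 and 10.56 in the fibrotic kidneys and at 4.41 to 4.74 in the healthy ones, Scgb1a1 is at 12.48 and 11.35 in the fibrotic kidneys, and Apoa1 is at 13.94 in healthy lung replicate 3.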

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

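The tests of paired probes, sex-dependent genes, other proximal tubule genes and lung transcripts were chosen only after the results they bear on were seen, whereas the tests of scaling and of other splits of the arrays were set before.

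The fibrosis change differed between kidney and lung for 5150 genes by the test of the difference itself, and among the 2144 genes called in both organs 1067 went the same way. A processing difference that sets healthy kidney and fibrotic lung arrays apart from fibrotic kidney and healthy lung arrays would act on probes of 1 gene unequally, and in 1219 genes with a pair of bright probes the kidney and lung changes of the difference between the probes correlated at r = -0.377 (bootstrap interval -0.445 to -0.305), and at r = -0.207 over all 5177 genes with a pair of detected probes, with array scores of 8.14 to 9.24 and 4.89 to 9.26 on 1 side and -10.5, -5.16 and -12.6 to -8.00 on the other. Such a difference acting on single probes was argued against as the whole cause, since 65.4% of the genes called on the brightest probe (370 of 566) were called in the same direction on the second, and 22 in the opposite direction. The scaling of the arrays was argued against as the whole cause as well, since at least 59.5% of the called genes were called in the same direction under each other scaling. Processing that moves both probes of a gene alike would pass the probe test, so it stays open as a part or the whole of the cause. It would part the arrays just as the tested difference does. It cannot be told apart here from a true difference between the organs or between obstruction and bleomycin. The array scores also lay on opposite sides for healthy and fibrotic arrays of each organ, and for healthy kidneys and healthy lungs. The kidney, lung and healthy organ contrasts are therefore open to such processing as well. Slides and processing days are not given in the sources used here.

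Androgen-dependent genes fell in the obstructed kidneys, which had Xist and lacked Y-linked transcripts while the healthy kidneys showed the reverse. A difference in sex may account for these falls, and so may loss of proximal tubule expression with injury. The 9 androgen-dependent genes outside the largest kidney falls had a median change of -3.35, against -1.03 for 44 other proximal tubule genes, a difference of -2.32 (two-sided permutation p = 0.00038, 100000 permutations), but the list was written after the falls were seen and the 9 include Cyp2e1, one of the largest shared falls, so this does not decide between them. Of the 44 other proximal tubule genes, outside the sex-dependent lists, 17 were lower and 3 higher, against 2005 lower and 2982 higher of all 12865 genes. The sex-dependent lists are short and were written after the data were seen, so a gene outside them can still depend on sex. This count therefore does not exclude sex as the whole cause of the other proximal tubule falls. Sex by these transcripts and obstruction coincide fully in the kidney arrays, and 4 female-biased genes went both ways (2 higher and 2 lower, median 0.43), so for any single gene the share of each stays open. The difference between the organs takes in this kidney change, so the same holds there.

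Scgb1a1, Sftpd and Sftpc were present in both obstructed kidneys and not above background in healthy ones. Lung RNA or tissue carried over would bring the abundant lung transcripts in 1 proportion. Against the lungs, the level of Sftpd corresponds to 1.60% to 3.09% and that of Scgb1a1 to 7.88% to 22.97%. Sftpd stood at log2 14.7 in healthy and 14.5 in fibrotic lung, and compression of so bright a signal, which was not tested, would raise its share. Of 20 transcripts abundant in lung, at a log2 level over 10, at least 40% (40% to 55% over both kidneys and both lung references) lay over 4-fold under the level that the Sftpd share gives, and 8 were not detected on each kidney. Against that reference, this argues against carry-over of whole lung as the whole source. Sftpd was taken after it was seen to be raised, which sets its share high and raises the percentage under it. The median share of the 20 was 0.44% to 1.05%, and a lower reference share was not tested. The limit of log2 10 was lowered from 12, where 4 transcripts gave 50%, and markers of muscle, fat, blood, adrenal and liver were left out, both after the result was seen. Expression of these genes in the obstructed kidney, or a carry-over of airway material with another makeup, stays open and was not tested.

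The other differences between the organs by the same test are given as values of kidney minus lung in log2 units. The largest were Fcrls 7.38, Scgb1a1 7.04, Ccl5 7.02, Serpina10 6.62 and Thy1 6.32 upward, and Acsm3 -6.74, Ugt1a7c -5.98, Slc39a8 -5.84, Nsdhl -5.73 and Slc22a30 -5.69 downward. Among the fixed and shared genes, Tgfb1 differed by 2.76 (adjusted p = 0.000684). Acta2 differed by 1.65 on the probe used (adjusted p = 0.0276), whereas another of its probes rose by 1.98 in lung (limma adjusted p = 0.0010). The call of the Acta2 difference was lost in the authors' processed intensities (0.74, adjusted p = 0.258). It was also lost without fibrotic kidney replicate 2 (1.37, adjusted p = 0.101), healthy kidney replicate 2 (1.35, 0.0545), healthy lung replicate 1 (1.44, 0.0627) or 2 (1.51, 0.0599), or fibrotic lung replicate 1 (1.62, 0.0550) or 2 (1.58, 0.0584). Col3a1 and Ccl7 were not above background in healthy kidneys, so their differences are fitted values, and for Ccl7 they do not settle which organ had the larger rise. Col3a1 differed by 1.27 (adjusted p = 0.0204), and the call was lost without background correction (0.14, adjusted p = 0.741), in the authors' processed intensities (0.32, adjusted p = 0.519), at an offset of 50 (0.52, adjusted p = 0.235) and without fibrotic kidney replicate 2 (0.92, adjusted p = 0.0853). Ccl7 differed by -1.32 (adjusted p = 0.0404), and the call was lost without fibrotic kidney replicate 1 (-0.61, adjusted p = 0.118), without each healthy kidney (-1.35 to -1.29, 0.0639 to 0.0753), each healthy lung (-1.41 to -1.27, 0.0514 to 0.0759) and each fibrotic lung (-1.42 to -1.15, 0.0534 to 0.0865), whereas without fibrotic kidney replicate 2 the difference was -2.03. It was also lost without a filter (-1.32, adjusted p = 0.0612) and without healthy lung replicate 3 and fibrotic lung replicates 1 and 3 together (-1.10, adjusted p = 0.214).

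Lists whose change differed had median differences of 2.50 for dendritic cells and MHC class II, 1.74 for interferon response, 1.70 for T and NK cells, 1.64 for immediate early and heat shock genes, 1.44 for tubular injury, 1.29 for B and plasma cells, 1.28 for endothelial cells, 1.22 for podocytes, 1.21 for TGF-beta, 1.14 for myofibroblasts, 1.02 for developmental and WNT genes, 0.90 for alveolar type 2 cells, -0.33 for fatty acid oxidation, -0.49 for oxidative phosphorylation and -0.81 for the proximal tubule. All 15 lost the call in camera with an estimated correlation (adjusted p = 0.47 to 0.72). In fry the proximal tubule (adjusted p = 0.054), oxidative phosphorylation (0.054) and fatty acid oxidation (0.061) lists did not pass, and without background correction tubular injury (0.136) and myofibroblasts (0.085) did not. Without fibrotic kidney replicate 2 the call was lost for tubular injury (median difference 0.84, camera adjusted p = 0.21), the proximal tubule (-0.06, 0.051), fatty acid oxidation (-0.08, 0.16), TGF-beta (0.77, 0.065) and myofibroblasts (0.81, 0.12), and without replicate 1 for podocytes (1.03, 0.099), with the proximal tubule at -1.44 and fatty acid oxidation at -0.72. Oxidative phosphorylation stood at -0.18 without fibrotic kidney replicate 2. The tubular injury call was also lost without healthy kidney replicate 1 (1.49, 0.0501) or 2 (1.37, 0.0511), healthy lung replicate 3 (1.41, 0.050002) or fibrotic lung replicate 3 (1.45, 0.0752), and the myofibroblast call without fibrotic lung replicate 2 (0.97, 0.056). The proximal tubule median was -1.26 without healthy lung replicate 3 and -0.49 without fibrotic lung replicate 1. Without healthy lung replicate 3 and fibrotic lung replicates 1 and 3 together, tubular injury lost the call (1.53, 0.185). Of 3755 probes without a gene name that were tested, 692 were higher and 734 lower in fibrotic kidney, and 719 higher and 757 lower in fibrotic lung.

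The 3 fibrotic and 3 healthy lungs, and likewise the 6 healthy arrays, were split into 3 and 3 in each of 10 ways. In both cases 1 of the 10 splits, the real one, reached the real count of genes, and the highest of the others gave 0. The splits are too few for a share under 0.05. For the healthy arrays, 4 splits part the organs of each mouse, and the highest of the other ones among these gave 0.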

How the results depend on the processing

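The setting without 3 lung arrays, the gene lists with arrays left out and the settings without lists of sex-dependent, lung, blood or liver genes were chosen after the data were seen, and the rest before. Of 226 called pairs of a named gene and a contrast, 0 reversed their direction in the settings run, and 17 lost the call in at least 1. In the authors' processed intensities the list medians of alveolar type 2 cells in lung (0.16) and in the organ difference (-0.20) and of fatty acid oxidation in lung (0.13) turned their sign, and relative to the median change of all genes (-0.32, 0.57 and -0.36) they did not. Over all settings the counts ranged from 2634 to 6029 genes for kidney (4987 as reported), 2070 to 6689 for lung (4863), 3807 to 6946 for the organ difference (5150), 4706 to 8731 between the healthy organs (7928) and 426 to 1741 for genes changed the same way in both organs (1067). With each array left out in turn the ranges were 3772 to 4812, 3835 to 4562, 4431 to 5250, 7116 to 7614 and 801 to 1418, where an obstructed kidney left alone is assumed to vary like the other groups. Without fibrotic kidney replicate 2, 3401 of the 3772 kidney calls were among those reported, in the same direction.

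A 2-fold threshold left 2634 genes in kidney, 2070 in lung, 4706 between the healthy organs and 426 in both organs, by construction. Scaling to a common median gave 1741 genes changed the same way in both organs; the cause was not tested. Without healthy lung replicate 3 and fibrotic lung replicates 1 and 3 there were 3114 genes in lung and 556 in both organs, with fewer arrays, and 4186 in the organ difference and 7442 between the healthy organs. With an estimated correlation 0 of the lists fixed before the data were examined passed in each contrast. Their lowest camera adjusted p was 0.241 in kidney, 0.154 in lung, 0.468 in the organ difference and 0.147 between the healthy organs. At the preset correlation 21, 20, 15 and 30 of them passed. With an estimated correlation 6, 6, 3 and 4 of them had an unadjusted p under 0.05, and fry called 26, 24, 21 and 37. Of the lists written after the data were seen, the androgen-dependent one passed in kidney with an estimated correlation (camera adjusted p = 0.026). That value is adjusted over 5 lists and those of the fixed lists over 41, so they do not compare directly. With listed genes removed and the p-values of the rest adjusted anew, the kidney count was 4963 without the sex-dependent lists and 4951 without 4 lung epithelial lists. The lung count without blood and liver lists was 4847. Such counts can move little by construction. They do not test the effect of sex or of other tissues on the remaining genes.

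With the mouse as a random replicate block the counts were 4988, 4865, 5126, 7861 and 1067, and as a fixed replicate block over the 6 healthy arrays 7627, against 8136 without it; the block changed none of the 235 results of named genes and none of the 92 list calls. Apart from left-out arrays, Cyp2e1, Ephx2, Mup2 and Ugt2b36 lost the kidney call with array weights (adjusted p = 0.0921, 0.1195, 0.0749 and 0.0769) and with a mean-variance trend (0.0521, 0.0720, 0.0728 and 0.0745), and Havcr1 in the authors' processed intensities (0.0619) and with only the kidney arrays (0.0910). Without a filter Ephx2 (0.0637), Mup2 (0.0550) and Ugt2b36 (0.0566) lost it, and without background correction Mup2 (0.0574). In lung, Ephx2 lost the call without background correction, in the authors' processed intensities, at an offset of 50, without a filter, with a mean-variance trend, with array weights and with only the lung arrays (adjusted p = 0.0531 to 0.0809). Of the pairs not called as reported, Acta2 in lung was called in 3 settings (adjusted p = 0.0472 with a common median, 0.0209 in the authors' processed intensities and 0.0010 with all probes), Scgb1a1 in lung in 3 (0.0326, 0.0076 in these intensities and 0.0268 with array weights), Ager in lung in 3 (0.0161 without background correction, 0.0488 with array weights and 0.0117 with only the lung arrays), Sftpc in lung in 2 (0.0450 with array weights and 0.0212 with only the lung arrays), Apoa1 and Mup3 in kidney with only the kidney arrays (0.0116 and 0.0041), and Sqle in kidney with all probes (0.00051). The cause was not tested. With each array left out in turn, 21 to 24 lists passed in kidney, 19 to 21 in lung, 11 to 18 in the organ difference and 28 to 31 between the healthy organs. Of the 92 list results, 86 lost the call with an estimated correlation, 4 with fry, which gained 1, and 3 without background correction. Array weights were lowest for the fibrotic kidneys, at 0.428 each, and highest for fibrotic lung replicate 1, at 3.04. A block for the slide was not run, since the slide is not given in the sources used here. Signal over background limits folds against groups below it, which are bounds, and the detection limit differs between arrays.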

Other observations

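The lists of cholesterol synthesis, platelet and liver genes in this part were chosen only after the results were seen, and the other lists were fixed before.

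Cholesterol synthesis genes moved apart between the organs. Of 17 genes, 8 rose and 1 fell in fibrotic lung, also adjusted over the list alone (median 1.27, camera adjusted p = 0.0025, and adjusted p = 0.23 with an estimated correlation), and 3 rose and 7 fell in fibrotic kidney, also adjusted over the list alone (median -0.52, camera adjusted p = 0.037, and adjusted p = 0.48 with an estimated correlation). The difference between the organs was lower in kidney for 11 genes and higher for 1 (12 and 2 adjusted over the list alone, median -1.06, camera adjusted p = 0.00016, and adjusted p = 0.091 with an estimated correlation). The lanosterol demethylase Cyp51 changed by 2.76 ± 0.31 (SE) in lung and -2.30 ± 0.34 in kidney, and Nsdhl by 2.52 ± 0.27 and -3.21 ± 0.30. Sqle, squalene epoxidase, rose by 1.62 ± 0.23 in lung, with -0.12 ± 0.26 in kidney (limma adjusted p = 0.76; another of its probes changed by -1.91, adjusted p = 0.00051).

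Platelet and megakaryocyte genes fell in fibrotic lung with the red cell genes, 8 lower and 0 higher of 10 (9 and 0 adjusted over the list alone, median -2.43, camera adjusted p = 3.6e-06, and adjusted p = 0.15 with an estimated correlation), among them the platelet glycoproteins Gp9 (-2.92 ± 0.18, SE) and Gp5 (-2.82 ± 0.19) and the integrin Itga2b (-2.37 ± 0.16). In kidney 1 of the 10 rose and 0 fell, also adjusted over the list alone (median 0.31, camera adjusted p = 0.66). The platelet chemokine Ppbp stood at 9.73, 9.54 and 10.14 in healthy lungs and at 5.09, 6.78 and 5.82 in fibrotic ones, and at 4.42 and 9.42 in the obstructed kidneys. Glycolysis and hypoxia genes rose in fibrotic lung, 11 higher and 3 lower of 24 (12 and 3 adjusted over the list alone, median 0.53, camera adjusted p = 0.0095, and adjusted p = 0.47 with an estimated correlation, and 0.063 without healthy lung replicate 3 and fibrotic lung replicates 1 and 3), and immediate early and heat shock genes rose in fibrotic kidney, 13 higher and 1 lower of 25 (14 and 1 adjusted over the list alone, median 1.08, camera adjusted p = 0.0019, and adjusted p = 0.40 with an estimated correlation). Without healthy kidney replicate 2 the latter median was 0.69.

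Single arrays carried transcripts of other tissues. Of 21 liver genes, the median in healthy lung replicate 3 was 4.87 above the mean of the healthy lungs, against -2.27 and -2.29 in replicates 1 and 2; 0 rose and 1 fell in fibrotic lung, where the change had a median of -2.32 (camera adjusted p = 0.030, and adjusted p = 0.72 with an estimated correlation). The same array had Mup2 at 14.81, against 5.52 and 6.24 in the other two. The heart myosin Myh6 stood at 12.09, 13.01 and 6.26 in healthy lungs and at 10.53, 9.89 and 10.88 in fibrotic ones. Eif2s3y stood at 9.41 to 9.75 in the healthy lungs, at 9.78 and 9.76 in fibrotic lung replicates 1 and 2 and at 4.44 in replicate 3, and Kdm5d, another Y-linked gene, at 4.45 and 4.82 in the obstructed kidneys and 5.85 to 6.39 in the healthy ones.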
